A study of Streptomyces chattanoogensis with 18 samples.

How the data were processed

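Gene expression was measured in *Streptomyces chattanoogensis* L10 and in its ∆adpAch mutant, each grown in liquid YEME medium and sampled at 16 h, 24 h and 36 h. The labels gave 6 groups of 3 arrays, 18 arrays in all, and the series' design text stated that the RNA came from separate cultures of each strain. The arrays were a custom 1-colour Agilent design, and per the labels' protocols total RNA was amplified and labelled with Cy3. The p-values below take the 3 arrays of a group as 3 cultures, as that text states, and the number of arrays limited their precision.

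Each array had a scanner file of Agilent Feature Extraction 10.7.3.1, run with protocol GE1_107_Sep09 per the file headers. Per the file headers, the processed signal of each spot was an intensity that had been background-subtracted and detrended within the array and was not normalised between arrays. The median spot and local background brightness were also intensity values, and detection, saturation and outlier status were given as other values, 0 or 1 per spot, per the file headers. The authors' value table held log2 values for 8233 probes, 60 of them controls. Its deposited log2 columns held nearly the same set of values once sorted (largest difference between columns 0.0017), so it was read as quantile-normalised. Its rank order matched that of the processed signal on each of the 18 arrays (Spearman 1), each column's median was 5.56, and its step was not stated in the labels.

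The design held 8173 probes of 60 bases, of which 7473 had 1 spot and 700 had 11 spots. Outlier spots were left out, the log2 processed signals of a probe's spots were averaged, and the array's 75th percentile over probes was subtracted. Probes shared 8137 systematic names, called features here, and the 36 features with 2 probes took the probes' mean. Of the 32 such features that were tested, the probes had the same sign of change in 30 at 16 h, 28 at 24 h and 24 at 36 h. A feature was tested when it was well above background on all 3 arrays of at least 1 group, which kept 7489 features. The share of probes well above background was 17.7% on mutant 36 h replicate 3 and 68.6% to 95.6% on the other arrays. Saturated spots numbered 0 on every array.

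The files do not pair the identifiers with gene names: every description reads Unknown and no probe has a mapped coordinate. None of the 27 gene lists fixed in advance therefore matched a feature (0 matched), the list tests were not run, and the *adpA* transcript could not be looked up in the mutant. Features are reported under the files' identifiers. For each strain comparison the text names the 2 highest and the 2 lowest fold changes among called features, and for every other comparison the highest and the lowest. Named features had to be well above background on at least 2 of 3 arrays in each group compared and to share their 60-base sequence with no other probe. The limit on identifiers was applied to each comparison, and these details were settled after the grouping but before any fold change was seen.

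One model was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, with 1 mean per group, and variances were moderated by empirical Bayes. Comparisons were mutant against wild type at each time, the change of that difference between successive times (an interaction), and successive times within each strain. P-values were adjusted by the Benjamini-Hochberg method over the 7489 features of each of these 9 comparisons. A feature was called at an adjusted p below 0.05 and a fold change of at least 2. Adjusted p-values are 2-sided and come from this limma fit. Where every array of 1 group was not well above background, the difference is a bound, computed as the brighter group's mean minus the dimmer group's mean of the higher of each array's lowest detected signal and the feature's own signal, and is written "at least N-fold". Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the files.

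The fit was tested on simulated data with 7489 features, 200 of them changed. It recovered, at log2 fold changes of 1.5, 2, 3 and 4 with 50 features each, 60, 74, 90 and 100% at 16 h, 62, 80, 96 and 98% at 24 h, and 60, 74, 100 and 96% at 36 h. False calls numbered 43 at 16 h, 0 at 24 h and 73 at 36 h. At 16 h and 36 h they exceeded the share of calls that the adjusted p threshold allows. SEs and adjusted p-values at those times may therefore be too small, and the counts too high. The median SD within a group was 0.68 in mutant 16 h and 0.75 in mutant 36 h, against 0.21 to 0.30 in the other groups. The fit shared each feature's variance over all groups. The simulated spread was set by these group SDs. False calls arose only at 16 h and 36 h, where the mutant SD was larger. No run with equal SDs was made. Comparisons between groups with small SDs may in turn have SEs that are too large and counts that are too low.

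The arrays lay on 5 slides. Slide 1 held the wild type 16 h arrays alone, slide 2 the wild type 24 h arrays with wild type 36 h replicates 1 and 2, and slide 3 wild type 36 h replicate 3 with mutant 24 h replicate 1. Slide 4 held mutant 16 h replicates 1 and 3, mutant 24 h replicates 2 and 3 and the mutant 36 h arrays, and slide 5 mutant 16 h replicate 2 alone. Slide 1 was scanned in scan 1, slide 5 in scan 3 and the other slides in scan 2, so both strains' 24 h and 36 h arrays shared a scan.

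The groups, tests, naming rule and most alternatives were chosen before the data were examined, apart from the later details of the naming rule given above. Alternatives were quantile or median scaling, the authors' value table, no filter, detection on all 18 arrays, the brightest probe per feature, the study's own criterion (unadjusted p below 0.05 with 2-fold), no fold minimum, a plain test per feature on the 6 arrays of a time, only those arrays in limma, a trended robust prior, slide as a random block or fixed term, and leaving out each array. Chosen after seeing the data were background correction by normexp (offset 50) on the median signal, since only 1 file had the mean signal that was planned, array weights, leaving out a pair of arrays, the slide terms for time comparisons, the letter in the titles as a block (at 16 h with B2 read as B) and fits within 1 slide.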

Results

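Transcript levels of *S. chattanoogensis* L10 mycelium were measured at 16 h, 24 h and 36 h of growth in the wild type and in the ∆adpAch mutant, with 3 arrays per strain and time. AdpA is a transcriptional regulator of development and secondary metabolism in streptomycetes, and the series asks which transcripts depend on it during growth. Levels are log2 signals relative to each array's 75th percentile, with the mean and SD of 3 arrays, and fold changes are given with their SE. Probes well above background made up 90.6% to 95.6% of all probes on the wild type 16 h arrays, 82.1% to 86.5% at 24 h and 73.8% to 84.6% at 36 h. In the mutant these shares were 68.6% to 86.9% at 16 h, 74.6% to 86.7% at 24 h and 17.7% to 90.2% at 36 h, the lowest being replicate 3. Pairs of arrays within a group correlated at 0.925 to 0.979 across features in the 3 wild type groups and at 0.944 to 0.971 in the mutant at 24 h. In the mutant they correlated at 0.803 to 0.962 at 16 h, where replicate 2 lay apart, and at 0.581 to 0.795 at 36 h. Features stand under the files' identifiers, which the files do not pair with gene names.

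At 16 h the mutant differed from the wild type in 3137 of 7489 features, 41.9%, with 1831 higher and 1306 lower in the mutant. The strongest rises among features that met the naming rule were in L10.orf6095 and L10.orf1775. That rule asked for detection on at least 2 of 3 arrays of each group and for no overlap between the groups. L10.orf6095 went from -4.09 ± 0.54 in the wild type to 1.61 ± 1.36 in the mutant (SD, n = 3 each), and L10.orf1775 from -3.45 ± 0.06 to 2.05 ± 0.63. The strongest falls among features that met the rule were in L10.orf5180, from 6.25 ± 0.47 to -1.59 ± 0.91, and L10.orf1191, from 5.10 ± 0.63 to -2.46 ± 2.41. The log2 fold change was 5.69 ± 0.69 (SE) for L10.orf6095 (limma adjusted p = 1.49e-05) and 5.50 ± 0.49 for L10.orf1775 (adjusted p = 7.1e-07). It was -7.84 ± 0.82 for L10.orf5180 (adjusted p = 3.54e-06) and -7.56 ± 0.88 for L10.orf1191 (adjusted p = 1.02e-05). By that rule all 3 mutant arrays lay on 1 side of all 3 wild type arrays for each of these 4 features. Every mutant array was above background for 3 of them, 2 of 3 for L10.orf1191. L10.orf5180 was measured by the probe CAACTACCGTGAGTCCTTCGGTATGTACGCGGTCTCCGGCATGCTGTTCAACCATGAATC, and L10.orf1775 by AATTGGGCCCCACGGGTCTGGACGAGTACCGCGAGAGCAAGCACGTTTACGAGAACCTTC.

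Decreases at 16 h were larger than increases. With features measured in 1 strain alone at their bound, the median size of the called changes was 2.26 on the log2 scale for the features lower in the mutant and 1.55 for those higher. At least 16-fold differences numbered 231 lower and 23 higher. Of the features called at no other time, 948 were higher at 16 h and 322 were lower. The median over all tested features was 0.44 above the wild type. Of all features, 4086 (54.6%) had no overlap between the strains' arrays, against a chance share of 10%. The wild type 16 h arrays filled a slide and a scan of their own, so slide and strain could not be told apart at this time, and 1755 features were called with slide as a random block. With normexp 81.7% of the calls were higher in place of 58.4%, and the plain test on the 6 arrays alone, with adjustment, called 860 higher and 932 lower. With detection on all 18 arrays 573 features were called, 76.4% of them higher. That filter dropped 193 features called lower and not detected on any mutant 16 h array. It also dropped 11 called higher and not detected on any wild type 16 h array. Its share of higher calls therefore does not test direction.

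At 24 h, 2995 features differed, 1500 higher and 1495 lower in the mutant. L10.orf5161 fell from 6.12 ± 0.23 to -3.79 ± 0.69 and L10.orf5152 from 7.76 ± 0.29 to -1.83 ± 0.03 (SD, n = 3 each). L10.orf0432 rose from -3.16 ± 0.62 to 4.25 ± 0.17 and CUST_7278_PI427711755, a probe with 11 spots and no orf identifier, from -0.97 ± 1.57 to 5.65 ± 0.38. The log2 fold changes were -9.91 ± 0.64 (SE) for L10.orf5161 and -9.59 ± 0.62 for L10.orf5152 (limma adjusted p = 1.64e-08 for both). They were 7.41 ± 0.57 for L10.orf0432 (adjusted p = 8.6e-08) and 6.62 ± 0.92 for CUST_7278_PI427711755 (adjusted p = 2.82e-05). In all 4 the 3 mutant arrays lay apart from the 3 wild type arrays, which the naming rule required. The probe of L10.orf5161 was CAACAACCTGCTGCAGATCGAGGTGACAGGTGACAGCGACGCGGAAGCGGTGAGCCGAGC, and that of L10.orf0432 was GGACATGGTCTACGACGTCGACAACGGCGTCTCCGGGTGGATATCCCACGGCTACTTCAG.

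The lower features at 24 h included 329 that were at least 16-fold lower, and the higher features 77 that were at least 16-fold higher, with bounded features at their bound. At least 4-fold lower were 940 and at least 4-fold higher 714. L10.orf5165, chosen after its values were seen, was not well above background in the mutant and was at least 928-fold lower there (limma adjusted p = 4.5e-09). Features with no overlap between the strains numbered 4650 (62.1%; chance 10%). With slide as a fixed term, which joined the strains through the 2 arrays of slide 3, 680 features were called, 230 higher and 450 lower, and CUST_7278_PI427711755 was no longer called (4.69, adjusted p = 0.212, from 2.4e-08 to 0.212 over all alternatives). The fold changes with that term correlated with those without it at 0.952 across features, while the median SE was 0.84 in place of 0.45. With detection on all 18 arrays 451 features were called higher and 98 lower. That filter dropped features not detected in the mutant, so this split does not test direction. With slide as a random block 2663 features were called and with normexp 1591, and no slide held both strains at this time.

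At 36 h, 2755 features (36.8%) differed, 1672 higher and 1083 lower in the mutant. Mutant 36 h replicate 3 had 17.7% of its probes well above background. Its 5th percentile of processed signal was 34.1, against 1.90 to 10.4 on the other arrays. Such a raised floor lifts dim features in the mutant mean, which may favour higher calls at this time. L10.orf1191 fell from 8.79 ± 0.11 to -2.68 ± 1.11 and L10.orf6989 from 8.20 ± 0.43 to -1.04 ± 0.89 (SD, n = 3 each). L10.orf3957 rose from -2.58 ± 0.32 to 4.88 ± 1.68 and L10.orf5951 from -2.97 ± 0.54 to 4.21 ± 0.38. The log2 fold changes were -11.48 ± 0.88 (SE) for L10.orf1191 (limma adjusted p = 1.15e-07) and -9.24 ± 0.39 for L10.orf6989 (adjusted p = 2.9e-10). They were 7.46 ± 0.80 for L10.orf3957 (adjusted p = 2.77e-06) and 7.18 ± 0.61 for L10.orf5951 (adjusted p = 3.07e-07). The 3 mutant arrays lay apart from the 3 wild type arrays in all 4 features, which the naming rule required. The probe of L10.orf1191 was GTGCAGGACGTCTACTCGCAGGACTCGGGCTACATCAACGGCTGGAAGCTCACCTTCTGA, and that of L10.orf3957 was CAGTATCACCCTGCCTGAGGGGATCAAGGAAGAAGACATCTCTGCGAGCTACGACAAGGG.

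At least 16-fold changes at 36 h numbered 122 higher and 184 lower, and the median size was 1.75 for the higher and 2.29 for the lower features, again with bounds. Features with no overlap between the strains numbered 3516 (46.9%; chance 10%). The median of all tested features was 0.32 above the wild type, and with quantile scaling, where it was 0.06, 50.8% of the calls were higher in place of 60.7%. With normexp 1229 features were called, 479 higher and 750 lower, and 1184 of them had been called in the same direction. With slide as a fixed term 570 features were called, 44.0% of them higher, and as a random block 2254. Only the 6 arrays of this time gave 1794 in limma and, in the plain test with adjustment, 848, 49.9% of them higher. With detection on all 18 arrays 548 were called, 87.2% of them higher, and no slide held both strains. That filter asked for detection on mutant replicate 3, so this share does not test direction.

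**Figure D1:**
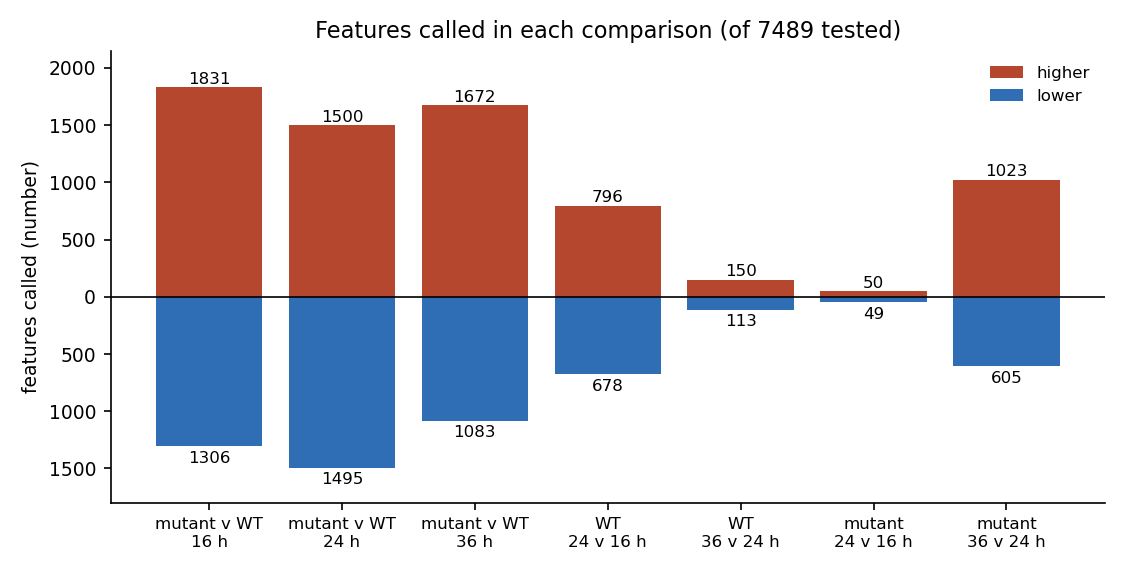
Number of features called in each comparison of strains at a time (left 3 bars) and of successive times within a strain (right 4 bars), with higher features above the line and lower ones below it. The strain comparisons called 3137, 2995 and 2755 of 7489 features.

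**Figure D2:**
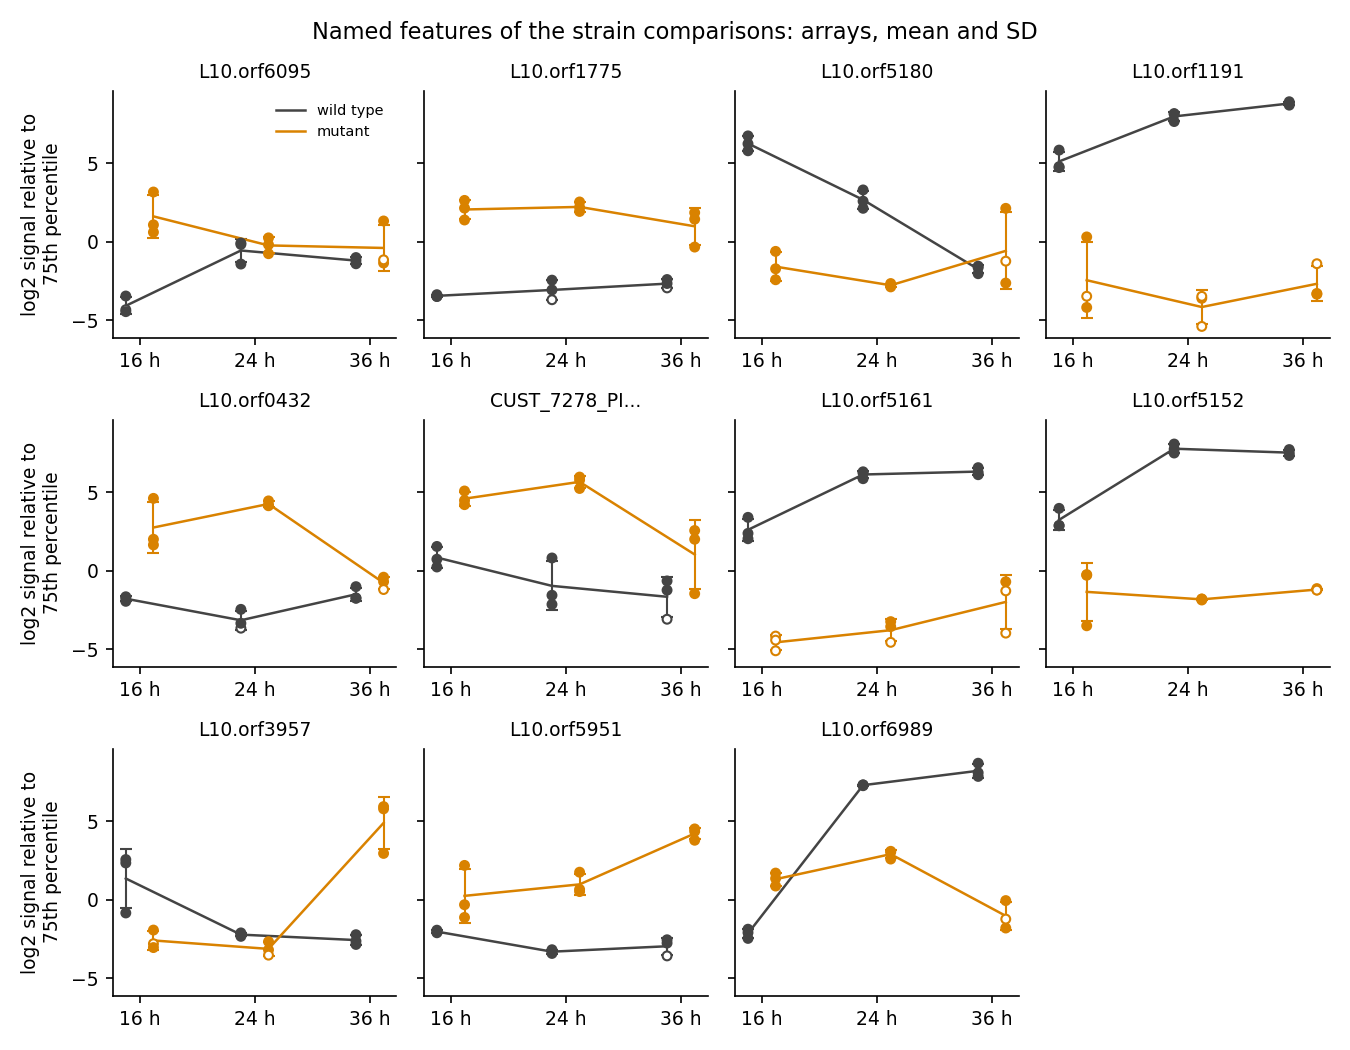
Log2 signal relative to the array's 75th percentile of the features named in the strain comparisons, by time, in the wild type (grey) and the mutant (orange). Points are the 3 arrays of a group, open where the feature was not well above background, bars are the SD and lines join the means, with L10.orf1191 at 8.79 in the wild type and -2.68 in the mutant at 36 h.

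Across the 3 times, 839 features were called in the same direction each time, 365 higher and 474 lower in the mutant. Independent lists of these sizes would share 81.9 higher and 37.7 lower features. L10.orf1775 was among the higher ones, with log2 fold changes of 5.50, 5.29 and 3.65 at 16 h, 24 h and 36 h. L10.orf1191 was among the lower ones, at -7.56, -12.13 and -11.48, and so was L10.orf5152 at -4.59, -9.59 and -8.72. L10.orf5161, also lower each time, was not well above background on any mutant array at 16 h and was at least 52.8-fold lower there (limma adjusted p = 7.7e-07), with log2 fold changes of -9.91 at 24 h and -8.30 at 36 h. L10.orf1191 at 24 h and L10.orf5161 at 36 h were well above background on only 1 of 3 mutant arrays, so their sizes there rest on signals near background. In all, 5271 features (70.4%) were called at 1 or more times. With slide as a random block 522 features were shared by the 3 times, with the plain test 205 (26.3% higher), with normexp 252 (23.8% higher in place of 43.5%) and with detection on all 18 arrays 130 (85.4% higher). The 85.4% does not test direction, since that filter asked for detection on every mutant array. The series' design text gives about 1400 genes as differentially expressed at all time points. At its criterion, read as an unadjusted p, 949 features were shared by the 3 times, and 3497, 3231 and 3099 were called at 16 h, 24 h and 36 h.

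Successive times shared more calls than the outer ones. Of the features called at both 16 h and 24 h, 1442 had the same direction and 89 the opposite one, and at 24 h and 36 h the numbers were 1678 and 71. At 16 h and 36 h they were 1009 and 272, of which 185 were lower at 16 h and higher at 36 h. The log2 fold changes correlated across features at 0.60 between 16 h and 24 h, 0.70 between 24 h and 36 h and 0.33 between 16 h and 36 h, where features are not independent replicates. At 24 h and 36 h most mutant arrays lay on slide 4 and most wild type arrays on slide 2. The wild type 16 h arrays lay on slide 1, so shared slides cannot be told apart from shared strain differences here. L10.orf6989 was called in opposite directions, higher in the mutant at 16 h (3.45 ± 0.39, SE) and lower at 24 h (-4.39 ± 0.39) and 36 h.

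Features detected on every array of 1 strain and on none of the other lay almost all in the wild type. Well above background on all 9 wild type arrays and on no mutant array were 56 features, and the reverse held for 0 features. Without mutant 36 h replicate 3, on which few probes were detected, the counts were 58 and 1. Of the 56 features, 30 were called lower at all 3 times and 47 at 2 or more times, while 8 were called lower at 1 time and 1 at no time. Detection over all probes also differed, at 90.6% to 95.6% on the wild type 16 h arrays and 68.6% and 69.6% on mutant 16 h replicates 1 and 3. That difference favours this direction, so the counts alone do not show that expression was lost in the mutant.

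Each of the 9 mutant arrays correlated more highly across features with the wild type arrays of 16 h, at 0.512 to 0.687, than with those of 24 h, at 0.402 to 0.599, or 36 h, at 0.394 to 0.596.

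**Figure D3:**
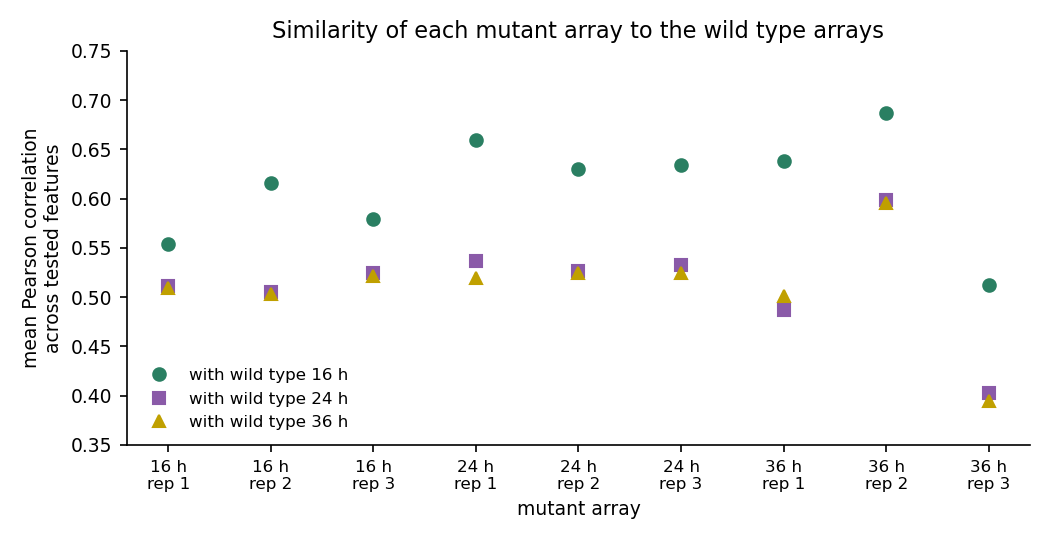
Mean Pearson correlation across tested features of each mutant array (x axis) with the 3 wild type arrays of 16 h (circles), 24 h (squares) and 36 h (triangles). All 9 mutant arrays lie highest with the wild type at 16 h, at 0.512 to 0.687.

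Called features were not spread evenly over the probe numbers of the array design. At 24 h, 22 consecutive features from L10.orf5144 to L10.orf5165, a stretch chosen after its values were seen, were all called lower in the mutant.

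**Figure D4:**
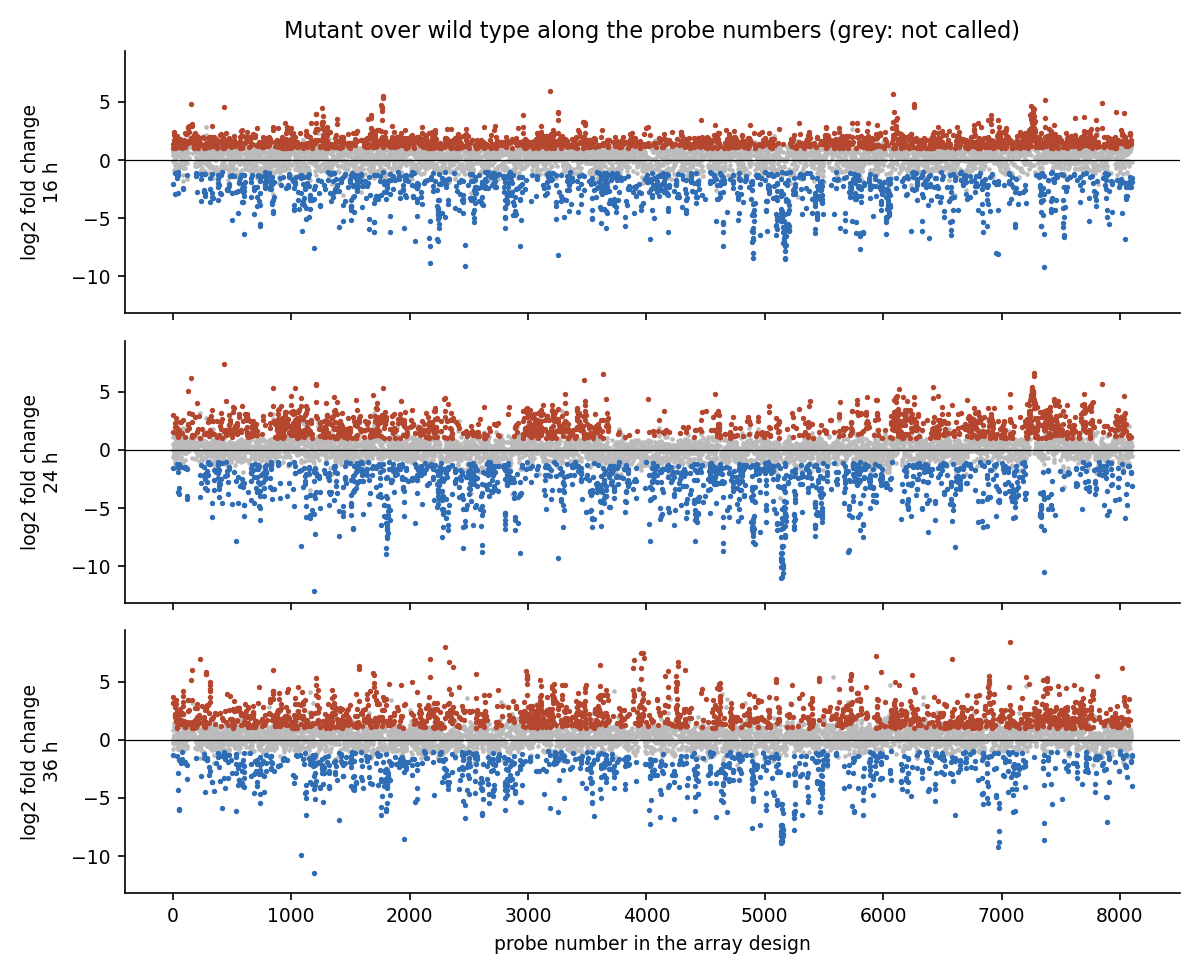
Log2 fold change of mutant over wild type at 16 h, 24 h and 36 h for each tested feature by its probe number in the array design, coloured where called and grey elsewhere. Coloured stretches include the 22 lower features from L10.orf5144 to L10.orf5165.

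The change of the strain difference from 16 h to 24 h was called in 1484 features, 603 upward and 881 downward. Among features detected on at least 2 of 3 arrays of each group, L10.orf5109 had the largest upward change, 7.53 ± 0.94 (SE, n = 3 per group, limma adjusted p = 0.000112): the wild type went from 3.98 ± 0.04 to -2.88 ± 0.65 while the mutant went from -1.57 ± 0.88 to -0.90 ± 0.93 (SD). L10.orf6989 had the largest downward change, -7.84 ± 0.55 (adjusted p = 4.6e-07), with the wild type going from -2.15 ± 0.30 to 7.29 ± 0.03 and the mutant from 1.30 ± 0.41 to 2.89 ± 0.27. The count was 3385 without mutant 16 h replicate 2, 891 and 941 without mutant 16 h replicates 1 and 3, 976 without wild type 24 h replicate 2, and 782 with slide as a random block. With quantile scaling 51.5% of the calls were upward and with the authors' values 52.5%, in place of 40.6%, and normexp called 3023, 15.5% of them upward. With detection on all 18 arrays 57.5% of 240 calls were upward. In 75 of the 1484 features a group was not well above background and a lower level there would shrink the change.

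From 24 h to 36 h the strain difference changed in 865 features, 519 upward and 346 downward. Among features detected in the same way, L10.orf3957 had the largest upward change, 8.37 ± 1.13 (SE, limma adjusted p = 0.00021), from -3.14 ± 0.43 to 4.88 ± 1.68 in the mutant against -2.23 ± 0.11 to -2.58 ± 0.32 in the wild type (SD, n = 3 each). L10.orf3188 had the largest downward change, -7.41 ± 0.66 (adjusted p = 5.8e-06), from 2.90 ± 0.50 to -2.09 ± 0.84 in the mutant against 1.35 ± 0.50 to 3.78 ± 0.24 in the wild type. The count was 1489 without mutant 36 h replicate 1, 1304 without mutant 16 h replicate 2, 572 without mutant 24 h replicate 2, 558 and 561 without wild type 36 h replicates 1 and 2, 491 with slide as a fixed term and 924 as a random block. With quantile scaling or the authors' values most calls were downward, with 41.6% or 41.7% upward, and with normexp 35.7% of 664 were upward. Without mutant 16 h replicate 2 and mutant 36 h replicate 3 49.3% of 1601 were. In 50 of the 865 a lower level of a group not well above background would shrink the change.

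Within the wild type, 1474 features changed from 16 h to 24 h, 796 higher and 678 lower at 24 h. L10.orf6989 rose by 9.44 ± 0.39 (SE, n = 3 each, limma adjusted p = 2.1e-10) and L10.orf5109 fell by 6.86 on the log2 scale (SE 0.67, adjusted p = 3.9e-06). All 3 arrays lay apart in both, which the naming rule required. The 796 features that rose in the wild type had a median change in the mutant of -0.35 over the same interval, against -0.26 over all features, and the 678 that fell had a median of 0.19. Calls in the mutant were too few with all arrays (99) to compare with these lists, and numbered 2622 without mutant 16 h replicate 2. Without that array, 76 of the 796 were called higher and 179 lower in the mutant, against 86.6 and 192 for independent lists. Of the 678, 46 were called lower and 117 higher, against 164 and 73.8. The difference between the strains' changes was itself called against the wild type's direction in 564 of the 796 and 405 of the 678, a count that shares the wild type arrays with the choice of features. Across all features the strains' changes correlated at -0.16. With normexp 901 features were called higher and 384 lower, and 1008 of the 1474 calls were made again in the same direction. That setting changed the signal used, the background correction and the offset together, and which of these moved the lists was not tested. With detection on all 18 arrays 83 were called higher and 119 lower. The wild type count was 524 with slide as a random block and 920 without wild type 24 h replicate 2, and the 16 h slide could not be told apart from the 16 h time.

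From 24 h to 36 h, 263 wild type features changed, 150 higher and 113 lower at 36 h. The shared variance gave this comparison the same median SE, 0.45, as the mutant one, although the mutant 36 h arrays spread more. The wild type count may thus be too low and cannot be compared directly with the mutant count. L10.orf1404 rose from 1.59 ± 1.37 to 5.53 ± 0.12 (SD; log2 fold change 3.94 ± 0.88, SE, limma adjusted p = 0.0194) and L10.orf5820 fell from 2.89 ± 0.97 to -1.81 ± 0.31 (-4.70 ± 0.59, adjusted p = 0.00041). In the mutant, 49 of the 150 rising features were also called higher and 11 lower, against 20.5 and 12.1 for independent lists, and 13 of the 113 falling ones were called lower and 31 higher, against 9.13 and 15.4. With quantile scaling 31 of the 150 were called higher, against 11.2, and 13 of the 113 lower, against 12.8. The wild type count was 764 within slide 2, 98 with slide as a fixed term and 317 as a random block. With normexp 48 features were called higher and 159 lower, and 101 of the 263 calls were made again in the same direction. The count was 465 without mutant 16 h replicate 2, 422 and 438 without mutant 36 h replicates 2 and 3, 116, 156 and 119 without wild type 24 h replicates 1, 2 and 3, and 133, 82 and 140 without wild type 36 h replicates 1, 2 and 3. L10.orf1404 was not called with the slide term or without 4 of the arrays, wild type 24 h replicate 1 and each wild type 36 h replicate (adjusted p from 9.1e-06 to 0.163 over all alternatives).

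Within the mutant, 99 features changed from 16 h to 24 h, 50 higher and 49 lower at 24 h. L10.orf6213 rose from 1.36 ± 0.76 to 4.33 ± 0.24 (SD; log2 fold change 2.98 ± 0.69, SE) and L10.orf7810 fell from 2.52 ± 0.81 to 0.01 ± 0.53 (-2.51 ± 0.59), both with a limma adjusted p of 0.0483. This count rested on mutant 16 h replicate 2: it was 2622 without that array, 0 without mutant 16 h replicate 1 or mutant 24 h replicate 1 or 2 (537, 828 and 1046 at an unadjusted p below 0.05 with 2-fold), 4 without replicate 3 of either group, 210 to 353 without each mutant 36 h array, 17 to 27 without each wild type array but 24 h replicate 1 (75), and 3216 within slide 4, which excluded it. With 1 array left out, L10.orf6213 and L10.orf7810 were called only where that array was mutant 16 h replicate 2 or a mutant 36 h replicate (adjusted p over all alternatives from 1.9e-05 to 0.282 and from 0.00036 to 0.216), and slide as a fixed term gave 1283 and as a random block 561. Higher calls made up 50.5%, but 31.1% without replicate 2, 32.9% within slide 4, 39.9% with slide as a random block, 449 of 1283 with it as a fixed term, 28.6% of 84 with detection on all 18 arrays, and 69.2%, 73.7% and 64.7% with quantile scaling, median scaling and the authors' values.

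From 24 h to 36 h, 1628 mutant features changed, 1023 higher and 605 lower at 36 h. L10.orf3957 rose by 8.02 ± 0.80 (SE, n = 3 each, limma adjusted p = 5.2e-06), and L10.orf7867 fell from 5.09 ± 0.40 to -0.74 ± 0.78 (SD; -5.83 ± 0.43, SE, adjusted p = 4.3e-07). L10.orf7867 stood at -0.54 ± 0.40 in the wild type at 24 h and -0.99 ± 0.19 at 36 h, so that it was higher in the mutant by 5.63 ± 0.43 at 24 h (adjusted p = 8.6e-08) and by 0.25 ± 0.43 at 36 h (adjusted p = 0.694). The strains' changes over this interval correlated at 0.04 across features. The count was 68 within slide 4, which held the 3 later arrays and 2 of the earlier ones, 1097 with slide as a fixed term and 1640 as a random block. Higher calls made up 62.8%, and 39.7%, 39.4% or 49.2% with quantile scaling, the authors' values or median scaling, 39.0% of 652 with normexp, 80.9% within slide 4 and 50.6% without mutant 36 h replicate 3.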

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

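Chosen only after the result was seen were the tests of a swap, of the own slide, of replicate 3 alone, of the scan and of the later wild type slide, as were the last 2 forms of the interaction relabelling, after a first form that had also moved labels at the unused time and gave smaller shares.

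Results are listed here because the strain difference at 1 time differed from that at the next by limma's interaction test. The count was 1484 features from 16 h to 24 h and 865 from 24 h to 36 h, or 3385 and 1304 without mutant 16 h replicate 2. From 16 h to 24 h the log2 difference between mutant and wild type moved by -5.37 in L10.orf6095 (SE 0.98, adjusted p = 0.00194), -4.57 in L10.orf1191 (SE 1.24, adjusted p = 0.0183) and 2.87 in L10.orf0432 (SE 0.81, adjusted p = 0.0216). It moved by -5.01 in L10.orf5152 (SE 0.87, adjusted p = 0.00138) and by -7.84 in L10.orf6989 (SE 0.55, adjusted p = 4.6e-07). In L10.orf5109 it moved by 7.53 (SE 0.94, adjusted p = 0.000112), in L10.orf3188 by -4.41 (SE 0.66, adjusted p = 0.00049), in L10.orf5820 by -5.49 (SE 0.84, adjusted p = 0.00061) and in L10.orf7810 by -4.19 (SE 0.83, adjusted p = 0.00326). From 24 h to 36 h it moved by 6.61 in L10.orf5180 (SE 1.15, adjusted p = 0.00184), -6.68 in L10.orf0432 (SE 0.81, adjusted p = 7.7e-05), 8.37 in L10.orf3957 (SE 1.13, adjusted p = 0.00021) and 2.89 in L10.orf5951 (SE 0.86, adjusted p = 0.0395). It moved by -4.85 in L10.orf6989 (SE 0.55, adjusted p = 4.4e-05), -7.41 in L10.orf3188 (SE 0.66, adjusted p = 5.8e-06), 6.27 in L10.orf5820 (SE 0.84, adjusted p = 0.000197) and -5.38 in L10.orf7867 (SE 0.61, adjusted p = 4.4e-05). L10.orf5820 was not well above background on any mutant 24 h array. With those arrays at the floor used for bounds it moved by -5.15 and then 5.94, and a lower level there would make both changes larger. Whether the difference moved in L10.orf5161 from 16 h to 24 h was left open, since its mutant level at 16 h is only a bound and a lower one would shrink the change.

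Strain labels were redrawn within the 2 times of each interaction, 100 relabellings with the real one included. As many features were called in 7 of 100 for 16 h to 24 h (real 1484, highest other 2078) and in 7 of 100 for 24 h to 36 h (real 865, highest other 2513). These shares do not test either count, since relabellings that turned most labels at 1 time add the strain differences of both times in place of subtracting them. With each feature's mean strain difference over both times removed, which leaves the interaction as it is, 2 of 100 reached 1484 (highest other 1990) and 1 of 100, the real one, reached 865 (highest other 0 by limma). At an unadjusted p below 0.05 with 2-fold, 3 of 100 reached the real 2678 from 16 h to 24 h (highest other 3187) and 1 of 100 the real 1973 from 24 h to 36 h (highest other 1736). This last form was chosen after the result was seen. From 16 h to 24 h another relabelling called more features than the real one, so chance was not excluded for that count. From 24 h to 36 h no other relabelling drawn reached the real count, which argues against chance in this form only. For features shared by the 3 times, 1 of 100 relabellings, the real one, reached 839. The highest other called 0 by limma (8 at an unadjusted p below 0.05 with 2-fold). This argues against chance for that count. Other relabellings count the strain difference as spread, which lowers their calls. The shares cannot tell strain from slide, since no slide held both strains at the same time. Comparisons of 3 arrays with 3 allow 10 splits, too few for a share under 0.05. The real split against the highest other split gave 3137 and 0 features for the strains at 16 h, 2995 and 0 at 24 h, 2755 and 0 at 36 h, 1474 and 0 for wild type 16 h to 24 h, 263 and 0 for wild type 24 h to 36 h and 1628 and 38 for mutant 24 h to 36 h, 1 of 10 splits each. At an unadjusted p below 0.05 with 2-fold, the highest other splits with 0 called 1560, 188, 945, 161 and 108 features in that order. For mutant 16 h to 24 h, 2 of 10 splits gave as many as the real 99, and the highest, 857, set mutant 16 h replicate 2 with mutant 24 h replicates 1 and 2 against 3 arrays of slide 4. What sets the arrays of that split apart was not tested. Within slide 4 the count by time was 3216.

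Mutant 16 h replicate 2 correlated with the mutant 24 h arrays at 0.937 on average and with its own group at 0.804, while replicates 1 and 3 correlated at 0.962. A swap with a mutant 24 h array is argued against, since each of those arrays correlated better with its own group than with replicates 1 and 3, by at least 0.0967. Noise of dim features is argued against by an excess of 0.182 on the 4846 features above background on all 6 arrays, and its own slide by a correlation with the mutant 24 h arrays of slide 4 that exceeded those of replicates 1 and 3, which share that slide, by 0.0996. A wrong label with no partner in these data, or a culture further along at sampling, may account for it, and neither was tested. Replicates 1 and 3 were also dimmer, with 75th percentiles of processed signal of 44.3 and 40.9. Replicate 2 had 180 and the mutant 24 h arrays 87.9 to 118, and whether this bears on the pattern was not tested.

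The mutant 36 h arrays differed among themselves, at 0.581 to 0.795. Replicate 1 correlated on average at 0.821 with the mutant 24 h arrays and at 0.753 with its own group. Replicate 2 correlated at 0.687 with the wild type 16 h arrays and at 0.688 with its own group, and replicate 3 best with its own group, at 0.646. Replicate 3, with 17.7% of its probes above background, is argued against as the whole source, because replicates 1 and 2 correlated at 0.795 where the lowest pair in the wild type groups and the mutant 24 h group reached 0.925. Noise of dim features is argued against by a correlation of 0.740 on the 5357 features above background on both and on the wild type 36 h arrays, where the lowest wild type pair reached 0.958. Cultures that differed in growth state at 36 h may account for it, which was not tested.

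The 9 mutant arrays, at every time, correlated best with the wild type at 16 h among the wild type groups, at 0.512 to 0.687, against 0.402 to 0.599 with 24 h and 0.394 to 0.596 with 36 h. Noise of dim features is argued against by a median excess of 0.111 (0.0477 to 0.154) on 4350 bright features, and a delay of the whole wild type course within the hours sampled by the slope of the mutant change from 16 h to 36 h on the wild type change from 16 h to 24 h, -0.0934 across features (-0.150 to -0.0379 with 1 array left out). A delay of some features stays open, since 145 of the 796 features that rose in the wild type from 16 h to 24 h were called higher in the mutant from 24 h to 36 h, against 109 for independent lists (67 against 59.2 with quantile scaling), while of the 678 that fell 67 were called lower against 54.8 and 120 higher against 92.6. The scan and the slide of the wild type arrays cannot be told apart from their time: that 0 of the 8 mutant arrays scanned with the later wild type arrays resembled those more restates the pattern, and the only wild type 36 h array on another slide correlated with the mutant arrays by -0.0201 relative to the other 2. The mutant strain may lack the changes that the wild type makes from 16 h to 24 h, a hypothesis that these data raise and do not settle.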

How the results depend on the processing

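Chosen only after seeing the data were normexp, array weights, the pair of arrays left out, the fits within a slide, the letter block, slide terms for time comparisons and the test alternatives for shared features. Named features gave 755 alternative values: 711 kept direction and call, 44 kept direction and lost the call, and 0 turned; 20 of the 24 pairs of feature and comparison were called in every setting that gave a value (detection on all 18 arrays gave one for L10.orf6213 alone), all but L10.orf6213, L10.orf7810, L10.orf1404 and CUST_7278_PI427711755. Letters in the titles, shared by wild type times and by the strains at 36 h and, with B2 read as B, at 16 h, did not pair the arrays (correlation of the deviations of same-letter arrays -0.294 to 0.110). With the letter as a block 876 and 70 features were called for wild type from 16 h and 24 h (L10.orf1404 not) and 1957 and 2642 for the strains at 16 h and 36 h. No paired analysis was possible for the other comparisons because the mutant 24 h titles hold no letter. The planned list tests and normexp on the mean signal were not run, lacking names and that column, and slide as a fixed term could give no value for the strains at 16 h, the interaction or wild type from 16 h, or the shared features. The cause was not tested except where stated. Detection on all 18 arrays, which left 1216 features and so gave fewer calls, called 573, 549 and 548 at 16 h, 24 h and 36 h for the strains, 240 and 154 for the interactions from 16 h and 24 h, 202 and 44 for wild type, 303 for mutant from 24 h and 130 shared. It kept only features detected on mutant 36 h replicate 3, where few probes were, so shares of higher or upward calls under it do not test direction. Normexp, whose offset of 50 compares with array 75th percentiles of 40.9 to 275, called 1591 at 24 h and 1229 at 36 h for the strains, 3023 for the interaction from 16 h, 1 and 652 for mutant, and 252 shared. The plain test with adjustment called 1792 at 16 h, 848 at 36 h and 205 shared, and only the 6 arrays of 36 h called 1794. Slide as a random block (correlation 0.331) called 1755 at 16 h, 522 shared, 782 for the interaction from 16 h, 524 for wild type from 16 h and 561 for mutant from 16 h. Slide as a fixed term, which widened the SE (median 0.84), called 680 at 24 h, 570 at 36 h, 491 for the interaction from 24 h, 98 for wild type from 24 h and 1283 for mutant from 16 h. Within a slide, with fewer arrays, counts were 764 for wild type from 24 h and 3216 and 68 for mutant. Array weights, with 0.0798 for mutant 16 h replicate 2, called 4471 for the interaction from 16 h, 2488 and 991 for wild type and 3302 and 905 for mutant. Without mutant 16 h replicate 2 and mutant 36 h replicate 3 the counts were 3992 and 1601 for the interactions, 2063 and 694 for wild type and 3141 for mutant from 16 h. Mutant 16 h to 24 h also gave 39 with quantile scaling, 19 with median scaling, 34 with the authors' values and 27 with no filter. With 1 array left out, the strain counts were 2432 to 3808, 2634 to 3205 and 2289 to 3063, the shared count 716 to 1027, the interactions 891 to 3385 and 558 to 1489, wild type 920 to 1769 and 82 to 465, and mutant 0 to 2622 and 1207 to 2390. The interaction from 16 h gave 891, 3385 and 941 without mutant 16 h replicates 1, 2 and 3 and 976 without wild type 24 h replicate 2, that from 24 h 1304, 572 and 1489 without mutant 16 h replicate 2, 24 h replicate 2 and 36 h replicate 1 and 558 and 561 without wild type 36 h replicates 1 and 2, and wild type from 16 h 920 without 24 h replicate 2. Wild type from 24 h gave 465, 422 and 438 without mutant 16 h replicate 2 and mutant 36 h replicates 2 and 3, 116, 156 and 119 without wild type 24 h replicates 1, 2 and 3, and 133, 82 and 140 without wild type 36 h replicates 1, 2 and 3. Mutant from 16 h gave 2622 without mutant 16 h replicate 2, 0 (by limma; 537, 828 and 1046 at an unadjusted p below 0.05 with 2-fold) without mutant 16 h replicate 1 and mutant 24 h replicates 1 and 2, 4 without replicate 3 of either, 210, 324 and 353 without the mutant 36 h ones, and 17 to 27 without wild type arrays other than 24 h replicate 1. Quantile scaling moved the median of all features from 0.05 to 0.19 at 24 h and from 0.32 to 0.06 at 36 h, from -0.34 to -0.10 and from 0.27 to -0.14 for the interactions, and in mutant from -0.26 to -0.06 and from 0.34 to -0.08. Signal over background left 204, 402 and 449 strain calls at 16 h, 24 h and 36 h with a group not well above background, at 36 h the wild type in 345 of them, and both strains in 2 at 24 h and 12 at 36 h.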

Other observations

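The test of runs against shuffled orders was chosen after the result was seen. Features whose probe numbers follow each other on the array design changed together. At 24 h, 658 called features lay in 89 runs of at least 5 consecutive probe numbers called in 1 direction, 42 runs higher and 47 lower in the mutant, and at 16 h and 36 h the runs held 469 and 585 features. The longest lower run at 24 h, chosen after its values were seen, took in 22 features from L10.orf5144 to L10.orf5165, which include L10.orf5161 and L10.orf5152. All 22 rose in the wild type from 16 h to 24 h, by a median of 3.88 on the log2 scale, and their median difference between mutant and wild type was -4.29 at 16 h, -8.30 at 24 h and -7.52 at 36 h with features detected in 1 strain alone at their bound. All 22 were lower in the mutant at 24 h under each of the 4 other scalings and background corrections run, with medians of fitted values from -8.90 to -5.90 against -9.10.

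The longest higher run at 24 h, also chosen after its values were seen, took in 37 probes from CUST_7237_PI427711755 to CUST_7273_PI427711755, of which 32 had 11 spots each and none an orf identifier. Their median difference was 3.23 at 16 h, where 33 were called higher, 4.51 at 24 h, where all 37 were, and 1.43 at 36 h, where 2 were. Their median level in the wild type was 1.16 at 24 h and in the mutant 5.79.

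Log2 fold changes of neighbouring probe numbers correlated at 0.45, 0.53 and 0.49 at 16 h, 24 h and 36 h, and at 0.08, 0.14 and 0.08 for numbers 10 apart. Placement on the array is argued against for probes with 1 spot, since the distance between the spots of neighbours was 1.01 times that of random pairs. Probes with 11 spots, among them 32 of the 37 in the longest higher run, were left out of that comparison. Probe GC content is also argued against, since the correlation at 24 h was 0.526 after its trend was removed and 0.527 before. None of 1000 shuffled orders (0) held as many features in runs at 24 h, and the highest held 58. A candidate explanation is that probe numbers follow gene order and that neighbours are transcribed or regulated together. The orf numbers exceed the probe numbers by 0 to 16 throughout, but the files place no probe on a genome, so this was not tested.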
